A study of Mus musculus with 2 samples.

How the data were processed

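The series measured DNase-seq, in which DNase I cuts open chromatin and the cut ends are sequenced, in hippocampal tissue of male B6CASTF1/J mice aged 14 days. The labels name the tissue as a layer of the hippocampus without saying which layer, and a further field says only hippocampus. This strain is an F1 hybrid of C57BL/6 and CAST/EiJ mice. Per the labels there was 1 group of 2 biological replicates, and each label speaks of 3 males. The labels give both replicates the same donor identifier and do not say which animals went into each.

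Per the deposited file descriptions, every file was made from an alignment of 1 library to mm10, which is GRCm38, so peaks and footprints were called per replicate and not on pooled reads. The aligner and the peak caller are not given in the sources used here. Each replicate had a longer and a shorter peak list, a footprint list and a list of stretches with a false discovery rate of the cut rate. The signal per peak was deposited by the authors without a stated unit. All peak values of a library were whole multiples of 1 step within a tolerance of 0.05 of a step, in 100% of peaks. The step was 0.00707 in replicate 1 and 0.00815 in replicate 2. Such values may be counts scaled by a constant per library, but no source says so or gives a constant. The p-value files deposited by the authors hold false discovery rates rather than raw p-values: the cut rate stretches are listed only under 0.05, and every footprint carries the same rate of 0.01. The lowest rate under each peak was under 0.05 in the longer list and under 0.001 in the shorter one, and 1 peak of the longer list of replicate 2 had no listed stretch. The longer list was used as the main list. The authors' value per peak was used to describe and rank peaks. Ratios of it were also taken between the replicates and between chromosome X and the autosomes, although its normalization is not stated.

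Genes and sequence came from GRCm38.p6 with GENCODE M21. Of 20852 protein-coding genes with the same symbol in the RefSeq table, 83.4% started within 1000 bp of the same position, all on the same chromosome, and no peak lay beyond the end of its chromosome. The 21911 protein-coding genes of chromosomes 1 to 19, X and Y were used. A promoter was 1000 bp either side of any annotated transcription start site. A peak or footprint was placed at a promoter first, then in an exon, an intron or between genes. Peaks were shared if they overlapped by at least 1 bp, and the sharing by chance came from 100 random placements of the same peaks within their chromosomes. Strength was compared by Spearman's rho across pairs of shared peaks. Footprints were shared if a footprint of the other replicate covered at least 50% of their length.

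The 23 gene lists held 322 different genes, of which Neurod1 and Pax5 each stood on 2 lists: pan-neuronal, glutamatergic neuron, dentate granule cell, CA pyramidal cell, GABAergic interneuron, astrocyte, oligodendrocyte precursor, myelin, microglia, endothelial and mural, choroid plexus and ependyma, progenitor and neuroblast, immediate early, forebrain transcription factor, Hox cluster, cerebellum and hindbrain, liver, striated muscle, erythroid, lymphocyte, germline, imprinted and housekeeping. For each list, the share of genes with a promoter peak in both replicates was compared with all other protein-coding genes by a 2-sided Fisher's exact test. Peaks outside promoters, in the gene and 10 kb either side, were counted per gene, and the median of a list was compared with 10000 random lists matched on decile of gene length by a 2-sided permutation test. The p-values were adjusted over the 23 lists by Benjamini-Hochberg, with a threshold of 0.05. For 25 consensus motifs, footprints with 5 bp added to each side were searched on both strands and compared with windows of the same length moved by 100 bp to each side and lying outside any footprint. Ratios have 95% intervals, Fisher's exact test was 2-sided and adjusted over the motifs, and a motif was called only if it passed 0.05 the same way in both replicates. A motif with 0 matches among the control windows got a lower bound computed against a floor of 3 matches per library. Shares have exact 95% binomial intervals.

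Lists, motifs, tests, the alternatives of the closing section and the rule for named genes were fixed before the data were examined. The rule took from each list up to 4 genes with the highest mean promoter value among those with a peak in both replicates, up to 2 genes with a peak in neither in the order of the list, and the genes with a peak in 1 replicate only. It also took the 10 protein-coding genes with the most shared peaks outside promoters and the genes nearest the 5 highest shared peaks outside promoters. Some genes that the rule takes are not reported here. A pair of motif alternatives was chosen after seeing the data: footprints inside peaks, and control windows weighted to the GC content of the footprints. The other alternatives were promoter windows of 500 and 2500 bp, gene flanks of 0 and 50 kb, the stronger part of each peak list split at its median, each replicate left out in turn, the shorter peak list, lists of equal length, stricter and looser overlap, 10000 random lists matched on decile of promoter CpG content, 0 and 10 bp added to footprints, controls 200 bp away, and footprints outside promoters.

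With 1 group of 2 replicates no test between groups and no test for outlying samples was possible. Genes, peaks and footprints of the same libraries are not independent replicates, so p-values across them describe these libraries, and intervals cover counting error only. The text descriptions deposited with each replicate hold no measurement and were used only to learn how the files were made. Reads of the CAST/EiJ and C57BL/6 chromosomes were not separated here, and a bias of the alignment to mm10 against CAST/EiJ alleles was not tested.

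Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. The list tests, overlaps, motif search, step size and matched comparisons of the replicates were tested on simulated data; the CpG-matched lists, the motif ratios, the random placements and the values for chromosome X were not. The Fisher test called 0 of 920 null lists drawn from the 21911 genes, and 84 of 120 lists of 14 genes (70%) whose share of genes with a peak was raised from 60 to 98 percent. The length-matched test called 0 of 40 null lists and 20 of 20 lists of 14 genes with 3 times as many peaks. The simulated counts were Poisson counts and mostly higher than the real ones, where the medians of random lists were only 0 to 2. How often the test finds such a difference in the real counts was thus not measured. GABAergic genes, with a median of 2 against 0.5, were not called. All 250 planted overlaps were found, and 0 of 250 overlaps of less than 50% of the length were called at reciprocal overlap of 50%. All 25 motifs were found, each planted on a strand picked at random. A planted difference of 0.15 in log2 ratio was recovered within 0.02, and a difference made by GC content alone was removed to within 0.02. Of 40 random peak sets, 3 lay beyond the 95% range of matched sets, and 19 of 20 sets raised by 0.2 lay above it.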

Results

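DNase I cuts marked open chromatin in hippocampal tissue of male B6CASTF1/J hybrid mice aged 14 days, labelled as a layer of the hippocampus without saying which. The data were 2 biological replicates of this 1 tissue, with no second group, so comparisons were made between the replicates and between groups of genes, regions and motifs within them. Replicate 1 had 115072 peaks with a median width of 205 bp, covering 27.8 Mb, and replicate 2 had 95711 peaks with a median width of 202 bp, covering 23.1 Mb. The authors' value per peak had a median of 0.594 in replicate 1 and 0.734 in replicate 2, with maxima of 55.9 and 83.8. In steps of the smallest unit found in each library, the median peak held 84 and 90 and the weakest held 7 in both. All positions are on mm10 (GRCm38), and genes are those of GENCODE M21. Values given as mean ± SD are the authors' value of the highest promoter peak (n = 2 replicates). The highest peak was taken in each replicate separately over all start sites of a gene. A promoter peak in both replicates thus need not be the same peak, and for Egr1 and Otx2 the peaks of the replicates did not overlap. As the scaling of the values is not stated, the SD may also hold a difference between the libraries as a whole.

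Neuronal promoters were open in both replicates. All 14 pan-neuronal genes had a promoter peak in both. Among them were Tubb3, a neuronal tubulin (chromosome 8, 123411424 to 123422015; 3.15 ± 0.793), and Syt1, the calcium sensor of synaptic vesicles (chromosome 10, 108497650 to 109010982; 2.67 ± 0.225). The value of the vesicle-fission gene Dnm1 (chromosome 2, 32308471 to 32353338; 4.77 ± 1.13) came from a window that also holds a start site of Ciz1. Of 14 glutamatergic genes 13 had a peak in both. These included the AMPA receptor subunit Gria2 (chromosome 3, 80681450 to 80802835; 3.12 ± 0.0452), the bHLH factor Neurod2 (2.69 ± 0.308) and the kinase Camk2a (2.35 ± 0.311). The vesicular glutamate transporter gene Slc17a7 (chromosome 7, 45163949 to 45176142) had a promoter peak of 0.926 in replicate 1 and none in replicate 2.

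Promoters of all 16 immediate early genes, which neuronal activity induces, had a peak in both replicates. Egr1 (chromosome 18, 34859823 to 34864984) stood at 6.98 ± 0.819, Homer1 at 5.97 ± 0.675, Fosb at 5.12 ± 0.857 and Dusp1 at 4.65 ± 1.05. All 16 forebrain transcription factor genes also had one, led by Pou3f3 (chromosome 1, 42695768 to 42703176; 4.73 ± 0.824), Lhx2 (3.4 ± 0.534), Lmo4 (3.31 ± 0.396) and Emx2 (3.24 ± 0.722). All 16 housekeeping genes had one as well. The ribosomal gene Rplp0 (chromosome 5, 115559467 to 115563727) reached 12.8 ± 2.43, Ppia 7.94 ± 2.12, the proteasome gene Psmb2 6.66 ± 0.884 and Actb 6.6 ± 0.646. Among all 21911 protein-coding genes, 13721 (62.6%) had a promoter peak in both replicates, 754 in 1 only and 7436 in neither. These 5 lists were higher than the other protein-coding genes by Fisher's exact test (adjusted p = 0.00492 for pan-neuronal, 0.0493 for glutamatergic, and 0.00326 for each of the immediate early, forebrain and housekeeping lists). None of the 5 was called against random lists of the same promoter CpG content (adjusted permutation p = 0.237, 0.106, 0.664, 0.378 and 0.856 in the same order), 1 of them, glutamatergic, having an unadjusted p under 0.05 (0.0276). The other 4 lists were already at 100%, against matched medians of 85.7% to 93.8%, so no share they could have had would have been called higher, and this comparison decides nothing for them. The glutamatergic call also ended in replicate 2 alone (adjusted exact p = 0.0517) and in the shorter peak list (0.0889), and the forebrain call ended in the shorter peak list (0.115).

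**Figure D1:**
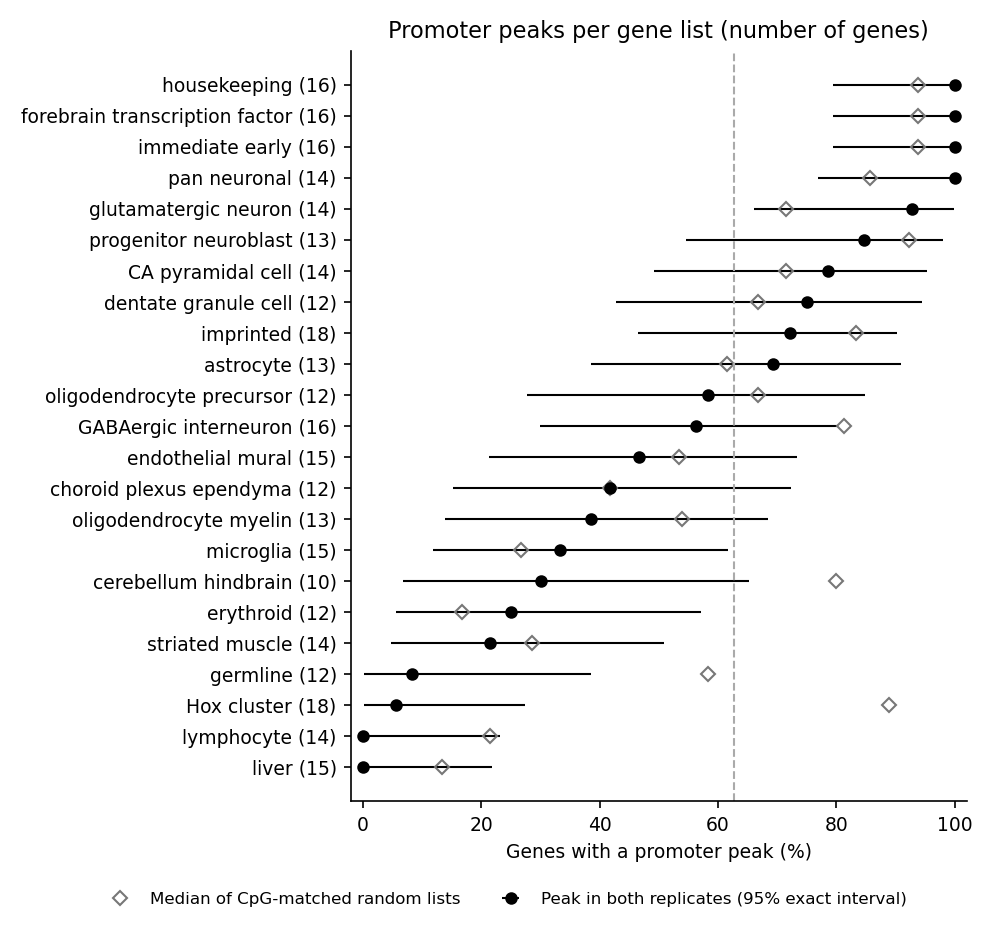
Share of the genes of each list, in percent, with a promoter peak in both replicates (points, with 95% exact intervals for counting error), the median of random lists matched on promoter CpG content (open diamonds) and the share among other protein-coding genes (dashed line); the number of genes is in brackets. The Hox cluster, at 5.56% against 88.9% in matched lists, cerebellum and hindbrain, at 30% against 80%, and germline, at 8.33% against 58.3%, lie far below their diamonds.

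Markers of the main hippocampal neuron classes were open in part. All values are from bulk tissue, and the lists hold marker genes of each class. Of 12 marker genes of dentate granule cells 9 had a promoter peak in both replicates. They included Neurod1 (chromosome 2, 79452521 to 79456751; 2.02 ± 0.0427), Prox1 (1.82 ± 0.0866), Stxbp6 (1.62 ± 0.559) and C1ql2 (1.41 ± 0.0293). Pdzd2 and Il16 had none in either and Lct had one only in replicate 2 (0.522). For markers of CA pyramidal cells it was 11 of 14, led by Pcp4 (chromosome 16, 96467606 to 96525793; 3.69 ± 0.376), Nectin3 (3.59 ± 0.854), Wfs1 (3.53 ± 0.789) and the kainate receptor gene Grik4 (3.21 ± 0.445). Mpped1 and Iyd had none, and Cacng5 had one in replicate 2 only (0.864). Markers of GABAergic interneurons had 9 of 16. The highest were the GABA-synthesising enzyme Gad1 (chromosome 2, 70553072 to 70602014; 2.16 ± 0.383), Cck (1.05 ± 0.0890), Pvalb (0.952 ± 0.187) and Adarb2 (0.930 ± 0.265). The vesicular GABA transporter gene Slc32a1 and Vip had none in either replicate, and Sst (0.326), Dlx1 (0.954) and Dlx5 (0.815) had a peak in replicate 2 only. None of these lists differed from other genes by Fisher's exact test (adjusted p = 0.636, 0.364 and 0.671). Against lists of the same CpG content, with a median of 81.3%, the GABAergic share of 56.3% was lower (adjusted permutation p = 0.0356), although in replicate 2 alone it was 75%. Progenitor and neuroblast genes, at 11 of 13, were not called either (adjusted exact p = 0.216). The topoisomerase gene Top2a (chromosome 11, 98992943 to 99024189) stood at 6.81 ± 0.02, Sox4 at 5.26 ± 0.304, Sox11 at 4.21 ± 0.428 and the cell cycle kinase Cdk1 at 3.87 ± 0.314. Eomes had no promoter peak, and the intermediate filament gene Nes had one in replicate 1 only (0.940).

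Glial and vascular markers had promoter peaks in between 33.3% of genes, for microglia, and 69.2%, for astrocytes. Of 13 astrocyte genes 9 had a peak in both replicates. The highest were Id4 (chromosome 13, 48261228 to 48266026; 2.89 ± 0.815), Sox9 (2.75 ± 0.186), the glutamate transporter Slc1a2 (2.08 ± 0.354) and Aldoc (1.43 ± 0.267). Aldh1l1 had none, Aqp4 (0.361) and the intermediate filament gene Gfap (0.608) had one in replicate 1 only, and Fgfr3 (0.954) in replicate 2 only. Oligodendrocyte precursor genes numbered 7 of 12, with Pdgfra (chromosome 5, 75152292 to 75198215; 2.19 ± 0.552), Olig1 (1.59 ± 0.256), Olig2 (1.12 ± 0.407) and Lhfpl3 (0.779 ± 0.282). Cspg4 and Sox10 had none, and Nkx2-2 had one in replicate 2 only (1.05). Myelin genes numbered 5 of 13, with Cnp (1.37 ± 0.143), Myrf (1.32 ± 0.358), Tspan2 (0.957 ± 0.134) and Enpp2 (0.856 ± 0.0699). Mog had none, and Mbp (1.16) and Cldn11 (0.717) had one in replicate 2 only. Microglia genes numbered 5 of 15, including Sall1 (1.88 ± 0.649), C1qc (1.56 ± 0.259) and the receptor gene Csf1r (0.837 ± 0.00375). Aif1 and C1qa had none, and Cx3cr1 (0.417), P2ry12 (0.410) and Ctss (0.240) had one in replicate 1 only. In replicate 1 alone 53.3% of the microglia genes had a promoter peak, and in replicate 2 alone 33.3%. Endothelial and mural genes numbered 7 of 15, with Pdgfrb (0.862 ± 0.199), Kdr (0.649 ± 0.188), Kcnj8 (0.533 ± 0.0643) and Slco1c1 (0.487 ± 0.129). Cldn5 and Tie1 had none, Pecam1 and Abcc9 (both 0.283) had one in replicate 1 only, and Flt1 (0.530) in replicate 2 only. In the choroid plexus and ependyma list it was 5 of 12, with the cilia regulator Foxj1 (chromosome 11, 116330704 to 116335399; 5.79 ± 1.26), Otx2 (0.715 ± 0.222), Kl (0.614 ± 0.0777) and Sostdc1 (0.564 ± 0.0130). Folr1 and Kcnj13 had none, Aqp1 (0.467) and Ccdc153 (1.01) had one in replicate 1 only, and Ttr (0.783) in replicate 2 only.

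None of these 6 glial and vascular lists passed Fisher's exact test (adjusted p = 0.778 for astrocytes and for precursors, 0.143 for myelin, 0.0563 for microglia, 0.364 for endothelium and 0.216 for choroid plexus), and none was called against CpG-matched lists. Microglia were lower than other genes with a promoter window of 500 bp (20%, adjusted exact p = 0.00433) and in the shorter peak list (20%, 0.0125). Endothelial genes were lower in the stronger part of each list (6.67%, adjusted exact p = 0.000289) and in the shorter list (13.3%, 0.00230), and so were choroid plexus genes (8.33% in both, 0.00134 and 0.00189).

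Promoters of genes of other tissues and body regions mostly lacked a peak in both replicates. The liver genes, such as the albumin gene Alb (chromosome 5, 90460897 to 90476602) and Apoa1, had a peak in 0 of 15, for which the exact interval reaches 21.8%. The lymphocyte genes, such as the T cell receptor complex genes Cd3e and Cd3d, had one in 0 of 14, for which it reaches 23.2%. Cd8a had one in replicate 1 only (0.262). Striated muscle genes had 3 of 14, namely Actn3 (5.84 ± 1.27, in a window shared with a start site of Zdhhc24), Myh7 (1.26 ± 0.126) and Tnni2 (0.929 ± 0.126). Acta1 and Ckm had none. Erythroid genes also had 3, of 12, including Tal1 (1.42 ± 0.341) and Epor (1.12 ± 0.0160). The globin genes Hba-a1 and Hba-a2 had none, and Hbb-bs had one in replicate 1 only (0.141). Germline genes had 1 of 12, Dazl (chromosome 17, 50279395 to 50293636; 1.77 ± 0.285), and none at Ddx4 and Zp3. Hox cluster genes, which pattern the trunk and hindbrain, had 1 of 18, Hoxb4 (chromosome 11, 96318267 to 96321638; 0.611 ± 0.254). Hoxa5 and Hoxa7 had none, Hoxa10 (0.877) had one in replicate 1 only, and Hoxa2 (0.481), Hoxa3 (0.351) and Hoxd13 (0.709) had one in replicate 2 only. The Hoxa3 window also holds a start site of Gm28308. The Hox share was 11.1% in replicate 1 alone and 27.8% in replicate 2 alone (adjusted exact p = 4.8e-05 and 0.00631), and the lymphocyte share was 14.3% in replicate 1 alone (0.000927).

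These 6 lists were lower than other protein-coding genes by Fisher's exact test (adjusted p = 7.2e-06 for liver and for Hox, 7.91e-06 for lymphocyte, 0.00891 for muscle, 0.0295 for erythroid and 0.000899 for germline). Against lists of the same CpG content, Hox and germline stayed lower (adjusted permutation p = 0.00153 for each, from the smallest p that the permutations can give). Liver, lymphocyte and muscle were not called (0.342, 0.0543 and 0.778). As liver and lymphocyte genes were already at 0%, against matched medians of 13.3% and 21.4%, no lower share was possible and neither could have been called, although the unadjusted p of the lymphocyte list was under 0.05 (permutation p = 0.0118). The erythroid share of 25% lay above the matched median of 16.7% (0.859). The erythroid call also ended with a window of 2500 bp (adjusted exact p = 0.240), in the stronger part of each list (0.0636) and in replicate 1 alone (0.0685). With a window of 2500 bp the shares were 11.1% for Hox, 25% for germline, 20% for liver and 14.3% for lymphocyte genes, all still lower (adjusted exact p = 6.76e-05, 0.0132, 0.00326 and 0.00143), and with 500 bp muscle genes had 0% (1.06e-05) and erythroid genes 8.33% (0.000927).

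Cerebellum and hindbrain genes had a promoter peak in both replicates in 3 of 10, including Cbln3 (2.00 ± 0.345, in a window shared with a start site of Khnyn) and the homeobox gene En2 (0.737 ± 0.203). Gabra6, a receptor subunit of cerebellar granule cells, and En1 had none, while Pax2 had one in replicate 1 only (0.453) and Atoh1 in replicate 2 only (0.530). This share was not called against other genes (adjusted exact p = 0.0830) but was lower than the 80% of CpG-matched lists (adjusted permutation p = 0.00153) and lower in the shorter peak list (20%, adjusted exact p = 0.0393). With a promoter window of 2500 bp it was 60% (adjusted exact p = 0.797). Imprinted genes, at 13 of 18, were not called (adjusted exact p = 0.572); Zrsr1 (3.12 ± 0.539), Peg3 and Usp29 (2.96 ± 0.126 for the same peak) and Igf2r (2.01 ± 0.0842) were the highest, and Grb10 and Ndn had no promoter peak.

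Away from promoters, the genes of forebrain transcription factors carried the most open sites for their length. Their median was 7.5 shared peaks per gene within the gene and 10 kb either side, against 1 in random lists of the same gene length. Glutamatergic genes had a median of 4.5 against 1.5, with 8 around Neurod2 and 7 around Camk2a. Imprinted genes had a median of 3 against 1, with 6 around Grb10 and 10 around Usp29. On the imprinted list Peg3 and Usp29, and Peg10 and Sgce, are neighbours with overlapping flanks, so a peak could count for both genes of a pair. The random lists did not mimic such neighbours. By permutation these 3 lists were higher (adjusted p = 0.00460, from the smallest p that the permutations can give, 0.0115 and 0.0245). Of the 23 lists 0 were lower, and none was lower at an unadjusted p under 0.05. A median cannot fall below 0, and the medians of the random lists were only 0 to 2. Lists with a random median of 0 could not have been lower, and liver genes, at 0 against 1, had an unadjusted permutation p of 0.947. For such lists the absence of a lower call decides nothing. The imprinted call ended in the gene body alone (adjusted permutation p = 0.418), with 50 kb either side (0.228), in the stronger part of each list (0.0653) and in replicate 1 alone (0.325). In replicate 2 alone 7 lists were higher, among them oligodendrocyte precursor (adjusted permutation p = 0.00230), GABAergic and immediate early genes (0.0268 each) and hindbrain genes (0.0269). Immediate early genes were also higher in the gene body alone (adjusted permutation p = 0.0383) and in the stronger part of each list (0.0199), and progenitor genes with 50 kb either side (0.0353).

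The remaining 20 lists were not called. Their medians, with those of random lists of the same gene length in brackets, were 4 shared peaks for pan-neuronal (2) and for dentate granule cell genes (1.5) and 2.5 for oligodendrocyte precursor genes (1). They were 2 for CA pyramidal (1), GABAergic (0.5), astrocyte (1) and hindbrain genes (0.5), and 1.5 for immediate early genes (0.5). The median was 1 for myelin, microglia, endothelial and choroid plexus (1 each), progenitor and Hox (0 each) and muscle, lymphocyte and housekeeping genes (0.5 each), 0.5 for germline genes (0.5) and 0 for liver (1) and erythroid genes (0). Dentate granule cell, GABAergic, oligodendrocyte precursor and immediate early genes had an unadjusted permutation p under 0.05 (0.0264, 0.0296, 0.0218 and 0.0356). The protein-coding gene models with the most shared peaks outside promoters were long. Gm20388 (chromosome 8, 119910841 to 124345722) is a model of 4435 kb with 221 such peaks, and the model of the growth factor receptor gene Fgfr2 (chromosome 7, 130162451 to 133123350) spans 2961 kb with 85. The promoter windows at their highest promoter peaks also hold start sites of Usp10 and Ctbp2, respectively. Peaks were counted over the whole span of a model, including any other genes within it, so these counts need not belong to Gm20388 or Fgfr2. Among the other genes of the first 10, the ion channel gene Asic2 and the splicing factor gene Rbfox1 had 40 each, Camta1 and the synaptic scaffold gene Dlg2 39 each, and Gm37240, Macrod2 and Zfhx3 38 each.

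The highest of the 5 strongest shared peaks outside promoters lay on chromosome 3 from 5860361 to 5860530 (37.3 ± 9.06), 109065 bp from Gm8797. The next lay on chromosome 9 from 123461881 to 123462140 in an exon of the mitochondrial leucyl-tRNA synthetase gene Lars2 (34.3 ± 7.87), and on chromosome 13 from 112578161 to 112578340 in an intron of Il31ra (25.4 ± 7.72). The list went on with chromosome 15 from 99735661 to 99736060 in an exon of the ceramide synthase gene Cers5 (23.6 ± 0.192) and chromosome 6 from 49236421 to 49236640 (21.8 ± 5.58), 7283 bp from Tra2a. In 4 of them, 100%, 58.1%, 65.1% and 69.3% of the 32-base words, for the peaks on chromosomes 3, 9, 13 and 6, occurred more than once in the reference, a property counted after the values were seen. The Cers5 peak had 0%, as had each of 5 random peaks from the strongest decile. Whether reads from other copies entered the values of the other 4 was not tested.

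**Figure D2:**
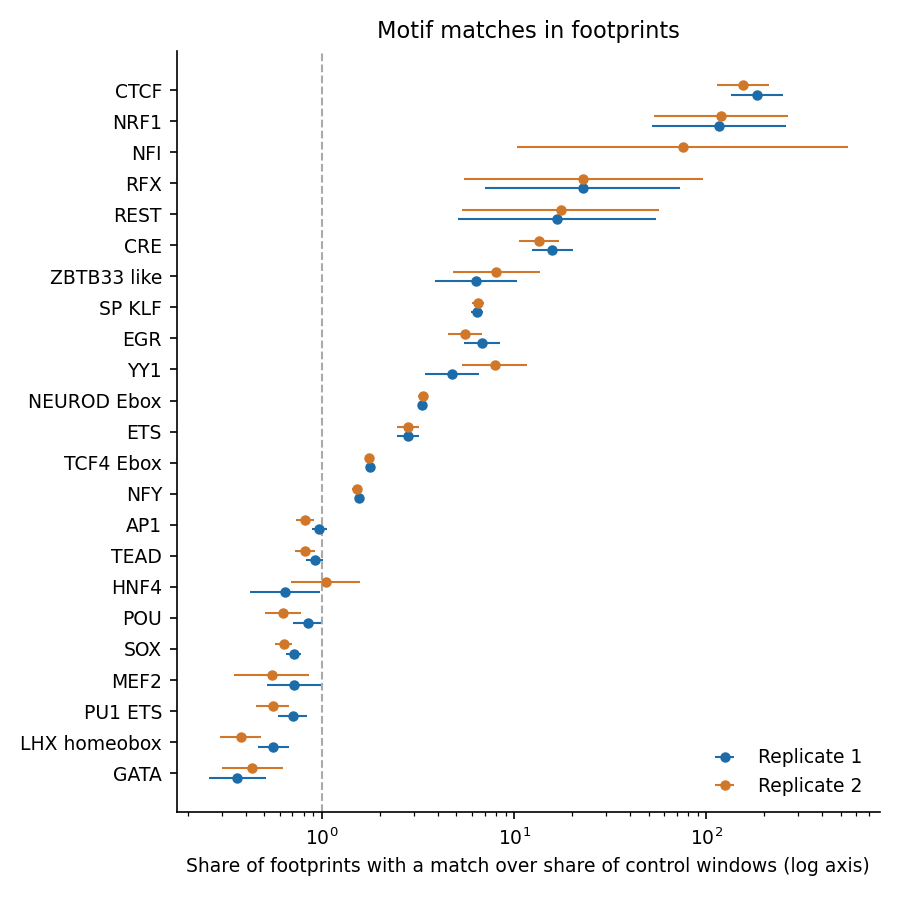
Share of footprints with a match to each consensus motif over the share of control windows, on a log axis, for replicate 1 (blue) and replicate 2 (orange), with 95% intervals that cover counting error only; the dashed line is a ratio of 1. CTCF, at 184 and 156, and NRF1, at 116 and 119, stand highest, and GATA, at 0.36 and 0.43, stands lowest in replicate 1; motifs with 0 matches in the footprints or in the controls have no point.

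Footprints, short protected stretches inside open chromatin, matched the motifs of several factor families more often than windows beside them. The insulator motif of CTCF was matched by 4438 footprints of replicate 1 (1.56%) and 3820 of replicate 2 (1.56%), at 184 and 156 times the control share. NRF1 stood at 116 and 119 and the cAMP response element at 15.8 and 13.5. The ZBTB33-like motif stood at 6.31 and 8.07, SP/KLF at 6.40 and 6.49, YY1 at 4.74 and 7.90, ETS at 2.79 in both and NFY at 1.56 and 1.51. EGR was at 6.79 and 5.52, the NEUROD E-box at 3.32 and 3.34 and the TCF4 E-box at 1.77 and 1.76. RFX (22.7, 95% interval 7.03 to 73.3, and 22.9, 5.45 to 96.0) and REST, the repressor of neuronal genes (16.6, 5.07 to 54.4, and 17.4, 5.34 to 56.9), rested on 2 or 3 control matches. The palindromic NFI motif was matched by 53 footprints and 0 controls in replicate 1, at least 29.3-fold higher against a floor of 3 control matches, and by 46 footprints and 1 control in replicate 2 (75.1, 10.4 to 545).

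The blood factor motif GATA (0.36 and 0.43), the homeobox motif (0.56 and 0.38), the myeloid PU.1 motif (0.70 and 0.55) and SOX (0.71 and 0.63) were matched less often in footprints than in controls. These 14 motifs higher and 4 lower passed Fisher's exact test in both replicates; the largest adjusted p was 5.4e-05, for PU.1. AP-1 (0.97 and 0.81), MEF2 (0.72 and 0.54), POU (0.84 and 0.63), TEAD (0.91 and 0.82) and the liver motif HNF4 (0.64 and 1.04) were not called, and HNF1 and p53 had 0 matches in footprints and controls. The p53 consensus is longer than the median footprint of 9 bp with 5 bp added to each side. Many footprints and controls could therefore not hold a p53 match. Footprints held 59.0% and 61.7% GC and control windows 53.2% and 55.1%. With controls weighted to the footprints' GC content, a setting chosen after seeing the data, the mean ratio was 70.0 for NRF1, 3.08 for SP/KLF, 3.65 for EGR, 0.63 for GATA and 0.83 for the homeobox motif. Among the motifs not called, the weighted ratios of replicates 1 and 2 were above 1 in both for MEF2 (1.21 and 1.02), POU (1.34 and 1.09) and TEAD (1.11 and 1.06), but not for AP-1 (1.13 and 0.988) or HNF4 (0.805 and 1.44). Other settings called some of them lower, by their mean ratios: POU with no bases added (0.43), with controls 200 bp away (0.66) and inside peaks (0.72), TEAD with no bases (0.47) and with controls 200 bp away (0.82), MEF2 outside promoters (0.56) and inside peaks (0.59), and AP-1 with no bases (0.67). The size of the ratios also depended on the bases added to each footprint. With no bases and with 10 bp, the mean ratio was 1178 and 79.2 for CTCF (170 with the 5 bp used here), 36.6 and 8.85 for the cAMP response element, 16.2 and 4.19 for SP/KLF and 12.1 and 3.41 for EGR. With no bases the ZBTB33-like motif stood at 23.1 and the NEUROD E-box at 5.14, and with 10 bp NRF1 stood at 42.3 and REST at 9.65. With controls 200 bp away REST was at 39.4 and the ZBTB33-like motif at 14.7, and outside promoters NRF1 was at 68.8, the cAMP response element at 7.28 and SP/KLF at 3.21. The ETS and YY1 calls ended outside promoters (mean ratios 1.71 and 4.56).

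Promoters held 39.6% of the 285181 footprints of replicate 1 and 46.3% of the 244137 of replicate 2, introns 29.8% and 26.3%, regions between genes 26.5% and 22.9%, and exons 4.14% and 4.56%. The median footprint was 9 bp wide in both replicates. Peaks contained 85.7% and 85.4% of the footprints, and 75.2% and 74.5% of peaks held at least 1. Among peaks, promoters made up 26.5% and 29.8%, introns 34.7% and 33.0%, regions between genes 32.7% and 30.2%, and exons 6.12% and 6.98%. Of the footprints of replicate 1, 31.8% were shared with replicate 2, and 37.5% the other way. Within shared peaks the shares were 38.8% and 42.0%, against 14.7% and 16.0% when footprints were placed at random within their peaks.

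Chromosome X, present as a single copy in males, had fewer and weaker peaks than every autosome. It held 17.5 peaks per Mb in replicate 1 and 14.0 in replicate 2, against autosomal medians of 46.2 and 38.2. The sparsest autosome was chromosome 3 (37.4 and 30.04) and the densest chromosome 11 (62.7 and 53.6). The median value of X peaks was 0.612 and 0.644 times that of autosomal peaks. The synaptic vesicle genes Syp (2.02 and 2.66) and Syn1 (1.29 and 2.26), chosen after their values were seen, lie on X and had promoter peaks in both replicates. Chromosome Y had 0.545 and 0.414 peaks per Mb of its whole length, with 1.99 protein-coding genes per Mb against 5.54 on X. On how much of Y reads can be placed was not assessed, so the cause of its low density was not tested.

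**Figure D3:**
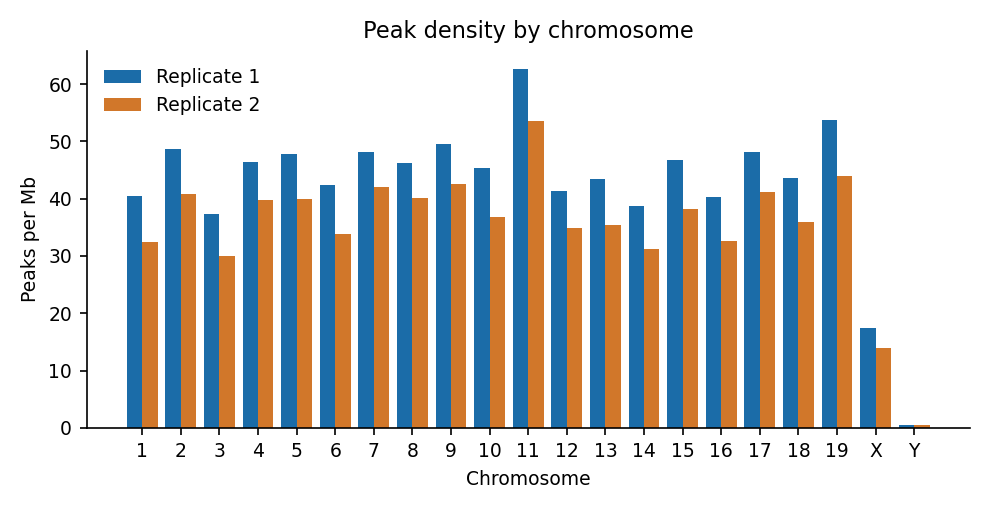
Peaks per Mb of each chromosome in replicate 1 (blue bars) and replicate 2 (orange bars) of the longer peak list. Chromosome X stands at 17.5 and 14.0, below the sparsest autosome, chromosome 3, at 37.4 and 30.04.

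Between the replicates, strong regions were shared and weak ones often were not. Top2a had a promoter value of 6.80 in replicate 1 and 6.82 in replicate 2, Gria2 3.15 and 3.09, and Rplp0 11.1 and 14.6. These are to be read beside a median ratio of replicate 2 to replicate 1 of 1.24 over shared promoter peaks, so equal values do not mark closer agreement. Of the peaks of replicate 1, 65.3% overlapped a peak of replicate 2, and 78.4% the other way, against 1.73% and 2.07% for random placements. The share ranged from 19.8% in the weakest decile of replicate 1 to 99.4% in the strongest, and from 36.5% to 99.5% in replicate 2. Promoter peaks were shared in 81.5% and 85.9%, intron peaks in 58.3% and 74.5%. Across 71381 pairs of shared peaks, which are not independent replicates, Spearman's rho of the authors' value was 0.938, with 0.976 at promoters and 0.905 elsewhere. The median log2 ratio of replicate 2 to replicate 1 was 0.19, with 0.31 at promoters and 0.11 elsewhere. As the scaling of the values is not stated, these ratios describe the lists only.

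**Figure D4:**
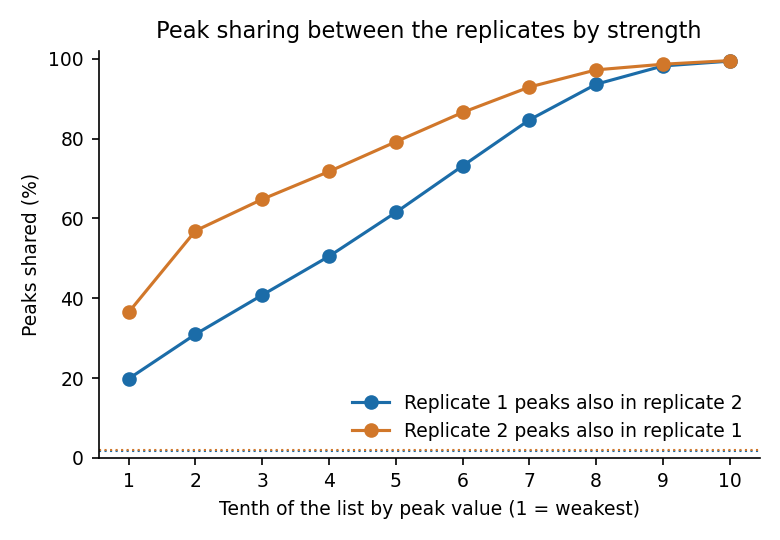
Share of peaks, in percent, that overlapped a peak of the other replicate, by decile of each list from the weakest (1) to the strongest (10) by the authors' value, for replicate 1 (blue) and replicate 2 (orange); dotted lines are the means of random placements, 1.73% and 2.07%. The share goes from 19.8% to 99.4% in replicate 1 and from 36.5% to 99.5% in replicate 2.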

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

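The deposited stretches with a false discovery rate under 0.05 were not used in the comparisons of the report, only to learn the threshold of each peak list and to look for weakly open promoters, and many of their bases lay outside the peaks of the longer list. In replicate 1 such bases covered 16.1 Mb, 38.0% of the 42.3 Mb listed, and in replicate 2 they covered 13.4 Mb, 38.0% of 35.3 Mb. Of these bases 67.8% and 67.1% lay within 150 bp of a peak, a distance chosen after the values were seen.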

How the results depend on the processing

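No paired analysis was possible because there is only 1 group. With 2 replicates and lists of 10 to 18 genes, only large differences in a share can be called, and the simulated lists raised to 98 percent were called in 70% of draws. Agreement of strength was the same in 2 of 2 alternatives and chromosome densities in 3 of 3. Calls on single lists were the same in 137 of 161 cases for promoters, with 9 newly called, 14 lost and 1 reversed, and in 104 of 115 for peaks outside promoters, with 7 newly called and 4 lost. Of 127 motif comparisons, 8 were newly called and 2 lost, and 14 ratios moved with GC-weighted controls, which had no test. The other 103 kept their call, or their ratio with these controls, but not always the size: the mean CTCF ratio of 170 was 1178 with no bases added and 79.2 with 10 bp. Footprints could not be split by strength, since the authors' value is constant, so that alternative was not run.

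Peak sharing of replicates 1 and 2 was 65.3% and 78.4% as reported. It was 47.1% and 56.6% at reciprocal overlap of 50%, 73.6% and 73.9% for lists of equal length, and 69.0% and 81.6% in the shorter lists. Peaks of the stronger part of each list overlapped the whole list of the other replicate in 89.6% and 94.9%. The share between the stronger parts themselves is not given. Footprint sharing (31.8% and 37.5%) was 38.6% and 45.2% at 1 bp and 28.0% and 32.7% at reciprocal overlap of 50%. With a promoter window of 500 bp, footprints lay at promoters in 34.2% and 40.5%, in exons in 5.29% and 5.88%, in introns in 32.8% and 29.4%, and between genes in 27.8% and 24.2%.

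The shorter peak list gave 3 promoter lists higher (5 as reported) and 10 lower (6). CpG-matched random lists gave 0 higher, but 4 of the 5 lists stood at 100% and could not have been called higher whatever their share. Against matched lists the erythroid share of 25% reversed to above its matched median (adjusted permutation p = 0.859). Outside promoters the lists called higher ranged from 2 without replicate 2 to 7 without replicate 1 (3 as reported). With no bases added to footprints, 7 motifs were lower (4 as reported). For all of these changes the cause was not tested.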

Other observations

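Gene families and the counts of repeated words, the finer and joint GC matching, the test of CpG-rich promoters on X and the shares of peaks and promoters in 1 replicate only were chosen after the results were seen; bounds for the other tests were written beforehand.

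Families named by gene symbol separated sharply at their promoters. Of 1134 olfactory receptor genes (Olfr) 23 had a promoter peak in both replicates (2.03%; 3.88% in replicate 1 alone), as had 3 of 330 vomeronasal receptor genes (Vmn), 0 of 35 bitter taste receptor genes (Tas2r), 10 of 110 keratin and keratin-associated genes and 23 of 100 cytochrome P450 genes (Cyp). In contrast, all 78 mitochondrial ribosomal protein genes (Mrpl and Mrps) had one, as had 31 of 32 complex I genes (Ndufa, Ndufb, Ndufs) and 38 of 40 proteasome genes (Psma to Psmd). So had 342 of 394 zinc finger genes named Zfp (86.8%) and 88 of 98 genes whose symbols start with Rpl or Rps and a digit. The symbol alone does not show that each of the latter encodes a ribosomal protein. Fisher's exact test against other protein-coding genes, adjusted over the families, gave 5.12e-135 for Vmn, 2.83e-15 for Cyp, 8.47e-16 for Mrpl and Mrps and 2.78e-26 for Zfp. Promoter CpG content differed in the same direction, with median observed over expected ratios of 0.152 for Olfr and 0.730 for Mrpl and Mrps. Over all protein-coding genes, the share with a peak went from 3.33% in the decile with the lowest CpG ratio to 97.8% in the decile with the highest.

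Several families with roles in neurons had promoter peaks more often than other protein-coding genes. Synaptotagmins (Syt) had a promoter peak in both replicates in 16 of 17 genes, glutamate receptor subunits (Gria, Grik, Grin, Grm) in 21 of 24, genes with symbols starting with Cacn in 22 of 26 and with Kcn in 72 of 94 (adjusted exact p = 0.00832, 0.0159, 0.0338 and 0.00832). Cacn and Kcn are symbols of calcium and potassium channel genes, but the symbol alone does not show that each gene encodes a channel. GABA receptor subunits (Gabr), at 13 of 19, did not differ detectably from other genes (0.813). These tests did not match CpG content. The median CpG ratio was 0.615 for Kcn, at 76.6%, while the CpG deciles with medians of 0.546 and 0.654 had peaks in 79.7% and 90.2% of genes. Glutamate receptor subunits, with a ratio of 0.607, lay between those deciles at 87.5%. Cacn, with a ratio of 0.757, lay at 84.6%, below the 93.2% and 96.1% of the deciles with medians of 0.729 and 0.793. Syt, with a ratio of 0.692, lay at 94.1%, above the 90.2% and 93.2% of the deciles with medians of 0.654 and 0.729. The clustered protocadherins (Pcdha, Pcdhb, Pcdhg), adhesion proteins of which single neurons express a few isoforms, had a peak in 6 of 54 (11.1%, adjusted exact p = 1.27e-14), with a median CpG ratio of 0.534, and the share was 25.9% in replicate 1 alone and 18.5% in replicate 2 alone. The interneuron factors of the Dlx family had one in 1 of 6, although in replicate 2 alone the share was 66.7%.

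Promoter peaks had a higher ratio of replicate 2 to replicate 1 than other peaks, by 0.20 on the log2 scale. If a background of cuts spread evenly over replicate 1 were the whole cause, peaks of equal strength would not differ. Within deciles of strength 0.136 (standard error 0.00303) remained, above the bound of 0.10 written beforehand, which argues against it as the whole cause. A part is not excluded, as such a background would also make the ratio rise with strength. Outside promoters the median log2 ratio was 0.0564 in the weakest decile of strength and 0.274 in the strongest. Different base composition of the libraries may account for most of the difference at promoters, since 0.0553 (standard error 0.00484) was left within deciles of GC content. This lies between the bounds of 0.05 and 0.10 written beforehand, so base composition stays open. With 100 GC bins 0.0496 was left, and with GC content and strength together 0.0590. No biological explanation was tested, as the replicates belong to the same group.

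Chromosome X had fewer and weaker peaks than any autosome. Fewer genes on X cannot be the whole cause, since X held 3.15 peaks per protein-coding gene in replicate 1 and 2.52 in replicate 2, below the lowest autosome, chromosome 7, at 3.46 and 3.02. A single X copy that gives a value of 0.5 times the autosomal one may explain the lower values, since CpG-rich promoter peaks on X had a median 0.519 ± 0.00836 times that of autosomes (SD, n = 2; bootstrap intervals 0.478 to 0.569 and 0.472 to 0.546), with single autosomes at 0.847 or more. Whether it also explains the number of peaks stays open: X peaks at the autosomal median strength, over autosomal peaks at 2 times that strength, both per gene, gave 0.784 ± 0.0191 (0.797 and 0.770, counting standard errors 0.0276 and 0.0287), about as close to the lower bound of 0.80 written beforehand as the counting error. No second group with another number of X copies was there to test the biological explanation, and a bias of the mm10 alignment against CAST/EiJ alleles was not tested.

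Hox, hindbrain and germline promoters had fewer peaks than promoters of the same CpG content. Weak openness below the peak threshold might account for this, and 2.86% of the 35 promoters without a peak in both replicates (1 of them) had a stretch at a false discovery rate under 0.05 in both. This test cannot decide, because 98.7% and 98.8% of all promoters with such a stretch have a peak, and nothing above that rate is listed. Of the 40 genes 12 had a peak in either replicate, 7 of them in 1 only (58.3%, against 5.21% over all protein-coding genes), but these lists were picked for few peaks in both and the 5.21% is not matched on strength or CpG content, so this decides nothing either. No biological explanation was tested.

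A different mix of cell types in the libraries might shift the ratios of cell type lists apart. Outside promoters, against random peak sets matched on strength, GC content and place, the microglia list lay at percentile 79.8 and the endothelial list at 84.4, neither beyond the 95% range. The glutamatergic list lay at 99.8 and the forebrain transcription factor list at 99.6 (adjusted permutation p = 0.0874 each), and oligodendrocyte precursors at 0.61 (0.0935), so none passed the threshold and the hypothesis stays open. With promoter peaks included, the forebrain list passed it (percentile 99.9, adjusted permutation p = 0.0414), with 132 of its 222 shared peaks above the matched median. The pan-neuronal list, with 141 shared peaks, then lay at 99.35 (adjusted permutation p = 0.132) and at 93.4 outside promoters (0.506). The Hox list, which marks no cell type of this tissue, lay at 99.1 with 12 shared peaks (0.132) and at 97.9 with 8 outside promoters (0.244). Such percentiles thus need not come from cell mix, though the Hox list rests on few peaks. Shares of all peaks in a gene and 10 kb either side found in 1 replicate only were not tested. They are to be read beside the 65.3% and 78.4% of all peaks that were shared. For precursors (31.8% in replicate 1 and 43.7% in replicate 2) they ran opposite to the percentile. They were about as far apart for Hox (33.3% and 60%) and erythroid genes (35.3% and 8.33%) as for microglia (40.6% and 11.4%). For GABAergic (33.0% and 44.6%), liver (36% and 32%) and muscle genes (29.7% and 35.9%) they were closer.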
